A study of Homo sapiens with 2 samples.

How the data were processed

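Gene expression was measured by RNA sequencing in 2 libraries of BHT101, a human cell line derived from an anaplastic thyroid carcinoma. Per the labels, 1 library came from control cells and 1 from cells with SETDB2 overexpression, and each group therefore held 1 library. The labels' protocols describe total RNA purified with TRIzol and a column kit and libraries made by a standard Illumina procedure. The vector, the time after its introduction, the library batch and the read length are not given in the sources used here.

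The authors deposited a table of whole-number read counts per gene and a table of FPKM values for each library, 4 tables in all. Bowtie2 2.0.6, TopHat2 2.0.9, Cufflinks 2.1.1 and Cuffdiff 2.1.1 are named in the submitters' processing notes, which do not say which step each served. The program that counted reads, its strand setting and its rule for reads that match several places are not given in the sources used here. Each deposited FPKM equalled the deposited count divided by the gene length in the same table and by 1 constant per library, 33825552.8 for the control and 33797559.4 for the SETDB2 library. Those constants were 1.00755 and 0.99249 times the total counts, so the FPKM table held no measurement that the counts did not. The tables listed 58735 genes. All of them were found in GENCODE release 29 with the same chromosome, start, end, strand and gene type, and 58708 carried the same name. Coordinates below are those of the tables and of that annotation, on the GRCh38 assembly.

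The deposited counts summed to 33572025 in the control library and 34053348 in the SETDB2 library. Counts were scaled with TMM factors from edgeR 4.0.16 (R 4.3.3), and DESeq2 1.42.0 supplied an alternative set of size factors. Neither program's test was run, because 1 library per group leaves no spread to estimate. No p-value, standard error or replicate check can be given for any difference here. The log2 ratio of the SETDB2 library over the control library used a prior count of 0.5 scaled to library size. Its 95% interval was the exact Clopper-Pearson interval of the ratio of 2 counts given the scaled library sizes, and it covers counting error only. Differences between cultures, between library preparations and between PCR copies are not in it.

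Genes with a summed count of at least 50 and at least 1 CPM (counts scaled to a common library size) in 1 library were kept, 14518 in all. At these depths a gene with a summed count near 50 reaches 1 CPM only if its counts are split unevenly. The lowest genes kept were therefore partly chosen for their imbalance. A gene was counted as higher or lower when its ratio was at least 2-fold and its interval excluded equality. This is a rule of size and not a test. Counts of genes past it were set beside 100 simulations in which the summed count of each gene was split by chance alone, and beside simulations with assumed gene-wise coefficients of variation of 0.1, 0.2 and 0.3 between cultures. Named genes followed a rule written before the data were examined. It took SETDB2 and U2AF1 with their overlapping or near-identical genes, and the 12 protein-coding genes higher and the 12 lower whose interval bound nearest 0 lay farthest from it. It also took 3 long non-coding genes in each direction, of which 1 is not reported here, and up to 4 members with the largest ratios in each gene list. Clone names, Y-linked genes and XIST were left out, and a gene with fewer than 10 counts in 1 library is given with both counts. Genes named outside this rule are marked as chosen after their values were seen.

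The 35 gene lists, 28 by member and 7 by name pattern, were also fixed before the data were examined. They covered splicing (spliceosome core factors, SR proteins and hnRNPs), H3K9 methylation machinery, reported SETDB2 targets, the neighbours of SETDB2 on chromosome 13, and thyroid differentiation. They also covered S phase, G2/M, p53 targets, apoptosis regulators, epithelial markers, mesenchymal markers, matrix proteases, interferon-stimulated genes, NF-kB targets and cytokines. Metabolic and stress lists held cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, the unfolded protein response with ATF4 targets, heat shock genes, and metallothioneins with NRF2 targets. Further lists held MAPK output, immediate-early genes, TGF-beta, WNT, NOTCH and YAP targets, cancer-testis genes, leukocyte markers, fibroblast and endothelial markers, and drug transporters with stemness genes. The pattern lists held ribosomal protein, mitochondrially encoded, ZNF, histone, HOX, keratin and snoRNA host genes. Each list's median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. The percentile describes these 2 libraries and is not a test of the condition. Chromosomes with over 300 genes were placed among 2000 such draws.

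For each gene, the GC content of its longest GENCODE 29 transcript and the share of its 75-base pieces found in no other gene's transcripts were computed from a sample of 1 in 4 pieces. The piece length is a choice made here, since the read length is not given. A smooth trend of the log2 ratio on GC content and then on gene length was removed with lowess (span 0.3, statsmodels 0.14.6) as an alternative added after the data were seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 did these steps.

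The steps were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed in each run and between 14374 and 14399 genes past the filter. The size rule recovered 45.0% of genes changed 2-fold, all 200 of those changed 3-fold or 4-fold, and 3.5% of those changed 1.5-fold. It called between 3 and 14 unchanged genes. The 95% intervals held the true ratio for between 95.2% and 95.6% of genes. These runs held counting error alone, the model behind the interval, so such coverage was built in. Without variation between cultures in them, the calls of unchanged genes and the coverage are no error rate for these 2 cultures. In 14518 genes, 11 of 200 lists drawn at random fell outside the middle 95% of matched lists, and 45 of 50 lists of 40 genes shifted by 0.15 on the log2 scale fell above it. The 200 lists came from the same ratios as the matched lists, so their share outside was built in too. It is no error rate for lists of related genes. Alternatives tried were total-count, DESeq2 and upper-quartile scaling, ratios from the deposited FPKM, a prior count of 2, other count filters and fold thresholds, protein-coding genes alone, and other ways to draw or summarise lists. Splicing itself was not analysed here, because counts per gene do not show which exons were joined.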

Results

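RNA sequencing compared BHT101 thyroid cancer cells that overexpressed SETDB2, a member of the SET domain family of histone H3 lysine 9 methyltransferases, with control cells of the same line. The series title names the splicing factor U2AF1 as the gene of interest. There was 1 library per condition and no replicate, so every value below compares those 2 libraries and intervals cover counting error only. The control library held 33572025 counts over 26299 genes and the SETDB2 library 34053348 counts over 26027 genes. The 10 most abundant genes took 6.32% and 5.97% of the counts and mitochondrial transcripts 5.06% and 5.0%.

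SETDB2 (ENSG00000136169, chromosome 13, 49444374 to 49495003) was higher in the library labelled as overexpressing it. Its count was 507 in the control and 1370 in the SETDB2 library, a log2 ratio of 1.43 (95% counting interval 1.28 to 1.58) or 2.69-fold. The downstream neighbours PHF11 and RCBTB1 did not follow it, with log2 ratios of -0.27 (-0.45 to -0.09) and -0.35 (-0.47 to -0.22). Over the 9 measured neighbours of SETDB2 on chromosome 13 the median log2 ratio was -0.06, at percentile 28.25 of matched random lists. SETDB2 shared none of its sampled 75-base pieces with another gene. Counts per gene do not separate transcripts of the vector from those of the cell's own gene.

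U2AF1 (ENSG00000160201, chromosome 21, 43092956 to 43107587), the small subunit of the factor that recognises the 3' splice site, was lower in the SETDB2 library. Its count was 1447 in the control and 377 in the SETDB2 library, a log2 ratio of -1.95 (-2.11 to -1.78) or 3.85-fold lower. The value is uncertain, because the assembly carries a near-identical copy, U2AF1L5 (chromosome 21, 6484623 to 6499261), and 7.73% of the 75-base pieces of U2AF1 were found in no other gene. U2AF1L5 went the other way, from 92 to 215 counts, a log2 ratio of 1.21 (0.86 to 1.59). The copy's share of the summed counts was 5.98% in the control (exact 95% interval 4.85 to 7.28) and 36.32% in the SETDB2 library (32.44 to 40.34). With both genes added together the counts were 1539 and 592, a log2 ratio of -1.38 (-1.52 to -1.25) or 2.61-fold lower. The large subunit U2AF2, which shared no piece with another gene, had 8830 and 9078 counts and a log2 ratio of 0.03 (-0.01 to 0.08). The related gene U2AF1L4 had 51 and 59 counts.

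The same arrangement of a gene on the long arm of chromosome 21 and a copy near the start of the chromosome was seen for other genes, a group chosen after its values were seen. CBSL, the copy of the cystathionine beta-synthase gene CBS, had 55 counts in the control and 505 in the SETDB2 library beside 1665 and 1317 for CBS, and their sum was 1720 and 1822. SIK1, a salt-inducible kinase, had 31 and 174 counts beside 653 and 633 for its copy SIK1B, and their sum was higher in the SETDB2 library at 0.23 (0.08 to 0.38). PWP2, a ribosome assembly factor, had 31 and 150 counts beside 1046 and 1323 for FP565260.1, and their sum was higher at 0.45 (0.33 to 0.56). SMIM11A had 275 and 11 counts, and its copy SMIM11B had 0 and 1, so that this sum also differed, with a log2 ratio of -4.47 (-5.50 to -3.70). GATD3A and GATD3B differed little, with 428 and 434 counts together. The pairs did not share sequence to the same degree. The share of pieces found in no other gene was 70.16% for GATD3A and 47.91% for CBS, against 6.68% for SMIM11A, so GATD3A is no like comparison for U2AF1.

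**Figure D1:**
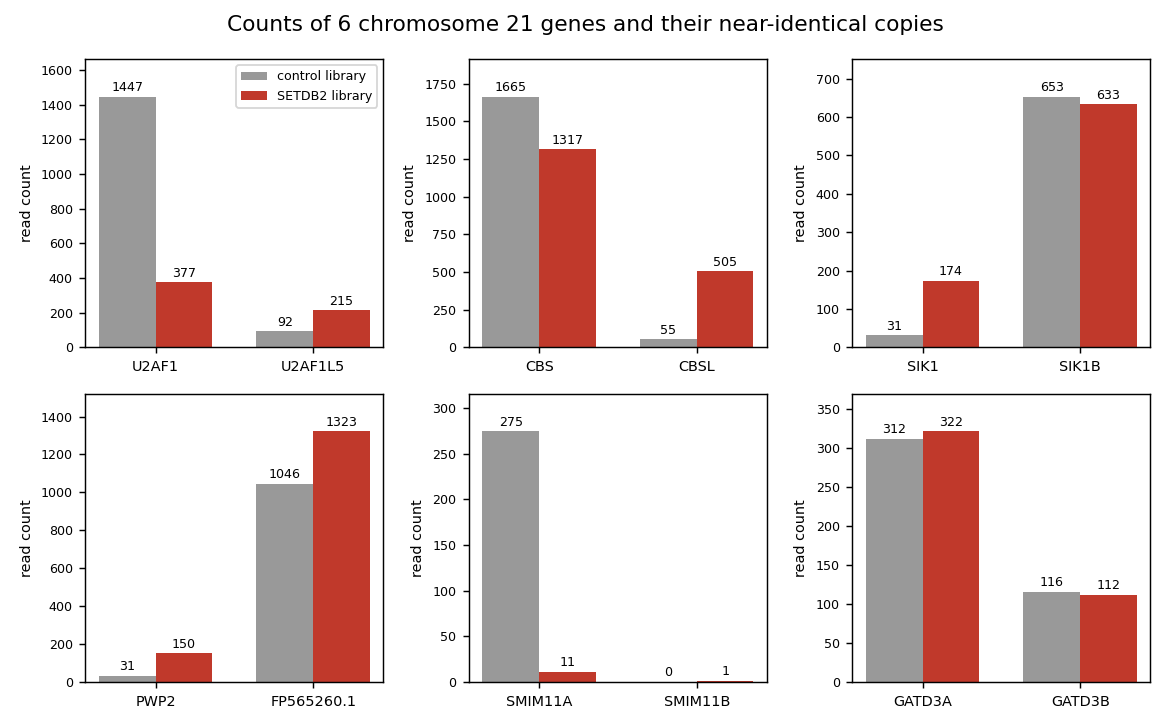
Read counts of 6 chromosome 21 genes and of their copies in the control library (grey) and the SETDB2 library (red), 1 library each, without scaling. Each panel has its own axis from 0. The pairs share sequence to different degrees. U2AF1 and SMIM11A were lower with their copies included, the sums for SIK1 and PWP2 with theirs were higher, and the sums for CBS with CBSL and for GATD3A with GATD3B were close in the 2 libraries.

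Most other spliceosome core factors were slightly higher in the SETDB2 library. Of 50 members, 40 lay above 0 and 10 below, and U2AF1 alone passed the 2-fold rule. SNRPF, an Sm ring protein, had a log2 ratio of 0.34 (0.26 to 0.43), and the splicing factors CWC15 and BCAS2 had 0.29 (0.16 to 0.41) and 0.27 (0.18 to 0.37). The median of the list was 0.11, at percentile 99.86 of 10000 matched random lists. The mean was 0.055 at percentile 92.96, inside the random range, and without U2AF1 it was 0.096 at percentile 99.88. SR proteins and hnRNPs had a median of 0.07 at percentile 87.91, with none of 39 past the 2-fold rule and SRSF1 at 0.35 (0.28 to 0.41).

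Across the 14518 genes kept, 155 were at least 2-fold higher and 234 at least 2-fold lower in the SETDB2 library, 2.68% in all. Among protein-coding genes these numbers were 93 and 137. Chance splitting of the counts alone gave 3.2 higher and 2.4 lower genes on average, with at most 9 and 7 in 100 draws. An assumed coefficient of variation of 0.2 between cultures and no effect of SETDB2 gave 176.8 and 172.1, a coefficient of 0.1 gave 9.8 and 9.7, and one of 0.3 gave 868.5 and 858.2. All these simulations kept the same 14518 genes and did not apply the count filter anew. Since the lowest of those genes were partly chosen for their imbalance, the simulated numbers can be too low. The test runs that did filter simulated counts, with counting error alone, called between 3 and 14 unchanged genes. For genes with at least 2000 counts the robust standard deviation of the log2 ratio was 0.16. The simulations gave 0.04 from counting error alone and 0.21, 0.41 and 0.62 with coefficients of 0.1, 0.2 and 0.3, so the spread of most high-count genes was below that of all 3 assumed values. For genes with fewer counts, and for single genes, the variation between cultures is unknown without replicates. The numbers varied with the count filter and the threshold. With a summed count of at least 200 they were 32 and 47, and at 4-fold they were 9 and 13.

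Among the protein-coding genes that ranked highest in the SETDB2 library, SERPINB2, the plasminogen activator inhibitor of type 2, had 486 and 1855 counts, a log2 ratio of 1.93 (1.78 to 2.07). AURKA, the mitotic kinase Aurora A, had 4553 and 10755 counts, a log2 ratio of 1.23 (1.18 to 1.28). It was the only 1 of 1400 genes with at least 10000 counts to pass the 2-fold rule, and the next largest ratio among them was that of the laminin gene LAMA5 at -0.91, a gene chosen after its value was seen. FRZB, a secreted WNT antagonist, had 103 and 289 counts, the metalloprotease gene ADAMTS9 15 and 65, and the teneurin TENM2 24 and 84. The cadherin CDH7 had 7 and 44 counts. CBSL, SIK1, PWP2 and the cancer-testis genes MAGEA2 (78 and 299) and SPANXA1 (5 and 47) completed the 12 with SETDB2, and in each of those 5 under 20% of the pieces were unique to the gene. The long non-coding genes SIRLNT and LINC02595 were also higher, with 88 and 216 counts and 15 and 44 counts. With an even split of the same counts CDH7, SPANXA1 and LINC02595 would not have passed the count filter, so they were kept only because they were uneven.

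Among the protein-coding genes that ranked lowest in the SETDB2 library, complement C3 had 78 and 13 counts, a log2 ratio of -2.55 (-3.56 to -1.73). The chemokine CX3CL1 had 1274 and 485, a ratio of -1.40 (-1.55 to -1.25), and KLHDC7B 2710 and 1020, a ratio of -1.42 (-1.52 to -1.31). The mucin MUC5B had 131 and 27 counts, the lysosomal protein LAMP3 57 and 13, and TMEM176A 92 and 17. TTC25 had 110 and 31 counts, NUDT8 50 and 11, and ALG1L and the extracellular matrix gene SPON1 each had 47 and 10. SMIM11A and U2AF1 completed the 12. The spans of C3, TMEM176A and ALG1L overlap those of GPR108, TMEM176B and FAM86JP, so reads from the shared parts leave these values less certain. LINC00471 (105 and 31), MID1IP1-AS1 (66 and 19) and ADAMTSL4-AS1 (39 and 11) were the long non-coding genes that ranked lowest. The last 2 overlap other genes on the opposite strand, and the strand setting is not given. ADAMTSL4-AS1 also overlaps MCL1 on its own strand, which had 24410 and 23447 counts, so both values are uncertain. With an even split of the same counts NUDT8, ALG1L, SPON1 and ADAMTSL4-AS1 would not have passed the count filter, so they were kept only because they were uneven.

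**Figure D2:**
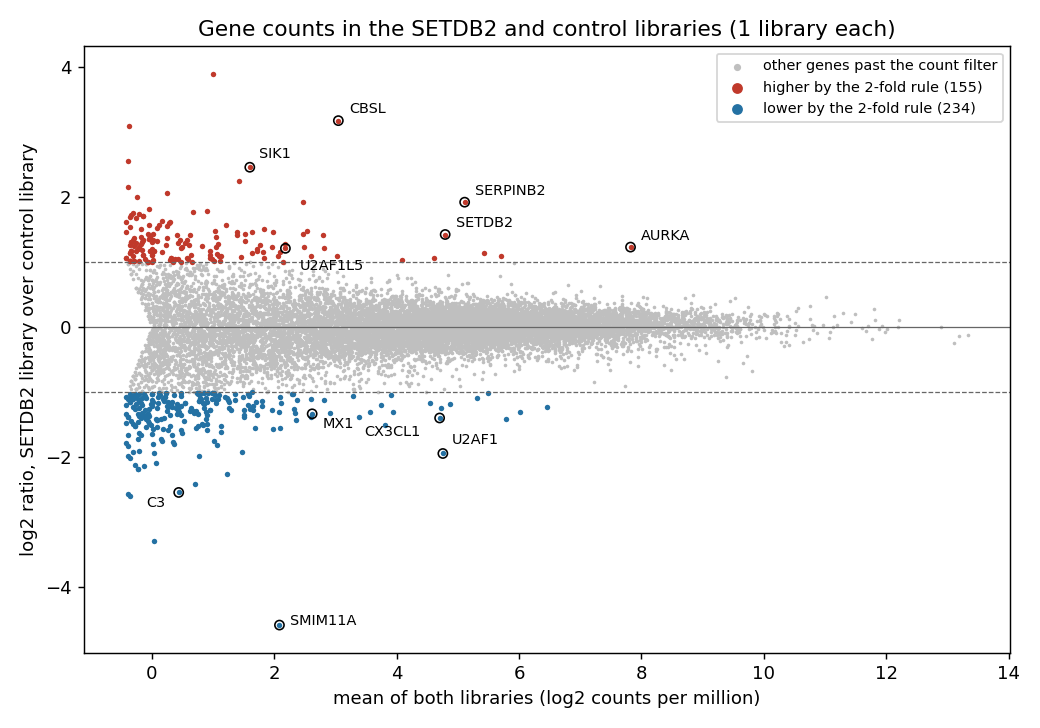
Log2 ratio of the SETDB2 library over the control library against the mean level of both (log2 CPM, counts scaled to a common library size), 1 point per gene past the count filter. Red and blue points are the 155 genes higher and 234 genes lower by the 2-fold rule, dashed lines mark 2-fold, and circles mark named genes; AURKA stands apart from genes of similar level.

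Interferon-stimulated genes were lower in the SETDB2 library almost without exception. Of 40 members 39 lay below 0, 6 passed the 2-fold rule, and the median log2 ratio was -0.52, below all 10000 random lists. MX1, an antiviral GTPase, had 297 and 118 counts, a ratio of -1.34 (-1.66 to -1.03). The RNA helicase gene DHX58 had a ratio of -1.31 (-1.54 to -1.09), RSAD2, which encodes viperin, -1.23 (-1.31 to -1.15), and TRIM22 -1.21 (-1.64 to -0.80). NF-kB targets and cytokines as a list did not stand apart, with a median of -0.02 at percentile 38.1, although the chemokine CCL5, which interferon also induces, had 736 and 297 counts and a ratio of -1.31 (-1.52 to -1.12).

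Cell cycle genes were higher by small amounts. Of 42 G2/M genes 40 lay above 0, with a median of 0.25 above all random lists. AURKA alone passed the 2-fold rule, and the next members were CDCA2 at 0.45 (0.34 to 0.56) and the kinetochore gene NDC80 at 0.44 (0.35 to 0.52). Of 40 S phase genes 35 lay above 0, none past the 2-fold rule, with a median of 0.16 above all random lists and CCNE2, a cyclin of the G1/S transition, at 0.60 (0.32 to 0.88). Replication-dependent histone genes had a median of 0.37 at percentile 99.85 over 16 measured members, with none past the rule. Of 24 p53 targets 16 lay below 0, with a median of -0.09 at percentile 4.77 and the antiproliferative gene BTG2 at -0.72 (-1.11 to -0.34). Apoptosis regulators had a median of 0.10 at percentile 95.16, with CASP6 at 1.00 (0.73 to 1.27).

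Stress and metabolic genes parted in direction. All 17 heat shock genes were higher, with a median of 0.29 above all random lists and none past the 2-fold rule. HSP90AA1, the inducible cytosolic HSP90, had 58692 and 81800 counts, a ratio of 0.47 (0.46 to 0.49). Of 30 nuclear-encoded oxidative phosphorylation genes 27 lay above 0, with a median of 0.13 at percentile 99.75 and NDUFB3 of complex I at 0.46 (0.33 to 0.58). The 13 mitochondrially encoded genes did not share this, with a median of -0.01 at percentile 15.42. Of 33 genes of the unfolded protein response and ATF4 targets 25 lay below 0, with a median of -0.12 below all random lists. Asparagine synthetase, ASNS, was at -0.55 (-0.69 to -0.41) and DDIT3, which encodes CHOP, at -0.40 (-0.52 to -0.28). Medians of cholesterol synthesis genes (0.09, percentile 96.2), glycolysis and hypoxia genes (0.09, percentile 95.74) and metallothioneins with NRF2 targets (0.11, percentile 96.71) lay inside the middle 95% of random lists. The mean of the glycolysis and hypoxia list lay at percentile 98.61, and the metallothionein and NRF2 list at percentile 98.27 with a summed count of at least 200. MT1M, a metallothionein, had 61 and 20 counts and ANKRD37, a hypoxia target, 12 and 41. ANKRD37 would not have passed the count filter with an even split of its counts.

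Medians of the thyroid, epithelial and mesenchymal lists lay inside the random range, while single members passed the 2-fold rule. The 9 measured thyroid differentiation genes had a median of -0.06 at percentile 42.84. DIO2, the type 2 deiodinase, had 1120 and 2397 counts, a ratio of 1.09 (0.99 to 1.20), and SLC26A4, which encodes pendrin, had 17 and 35. The count filter would have left out SLC26A4 had its counts been split evenly, so its ratio was partly set by the filter. Epithelial markers had a median of 0.05 at percentile 72.69, and MAL2 alone passed the 2-fold rule with 3111 and 1264 counts, a ratio of -1.31 (-1.40 to -1.21). Mesenchymal markers had a median of 0.06 at percentile 79.91, while their mean of 0.12 lay at percentile 99.13, outside the range. Collagen COL1A1 had 535 and 1126 counts, and fibronectin, FN1, the other way, 37034 and 23188, a ratio of -0.68 (-0.71 to -0.66). Matrix proteases and invasion genes had a median of -0.02 at percentile 9.73, with MMP1 (26 and 67) and ADAMTS1 (55 and 140) higher and the integrin ITGB4 (1379 and 610) lower. Keratin genes had a median of 0.11 at percentile 92.65, with KRT4 (13 and 43) higher and KRT16 (201 and 90) lower. KRT4 too would not have passed the count filter with an even split.

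Genes of the H3K9 methylation machinery had a median of 0.07 at percentile 88.13, with none of 27 past the 2-fold rule and SETDB1, the paralog of SETDB2, at -0.37 (-0.46 to -0.27). The 5 measured genes reported elsewhere as SETDB2 targets had a median of -0.04 at percentile 44.38. TGF-beta, WNT, NOTCH and YAP targets had a median of 0.02 at percentile 49.98, with LEF1 at 13 and 45 counts, while their mean of 0.16 lay at percentile 99.37. LEF1 would not have passed the count filter with an even split of its counts. MAPK output genes had a median of 0.01 at percentile 33.77, and immediate-early genes -0.03 at percentile 24.25. Cancer-testis genes had a median of 0.03 at percentile 65.36, drug transporters and stemness genes 0.10 at percentile 87.9, and HOX genes 0.14 at percentile 94.44, with percentile 98.93 without the count filter and below 80 with a summed count of at least 200. The 428 ZNF genes had a median of -0.02 at percentile 32.42, with ZNF681 and ZNF626 past the 2-fold rule. Host genes of snoRNAs had a median of -0.07 at percentile 7.92. Ribosomal protein genes, with a median of -0.02, lay at percentile 0.24 of lists matched on expression and at percentile 23.26 of unmatched lists. The 3 measured leukocyte markers had a median of -0.55 at percentile 11.5, or 1.31 of unmatched lists, and the 5 measured fibroblast and endothelial markers 0.43 at percentile 99.96, led by COL1A1 and COL1A2, which the mesenchymal list also holds. Only 5 of its 17 members passed the count filter, and without the filter its direction turned, with a median of -0.39 at percentile 2.33.

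**Figure D3:**
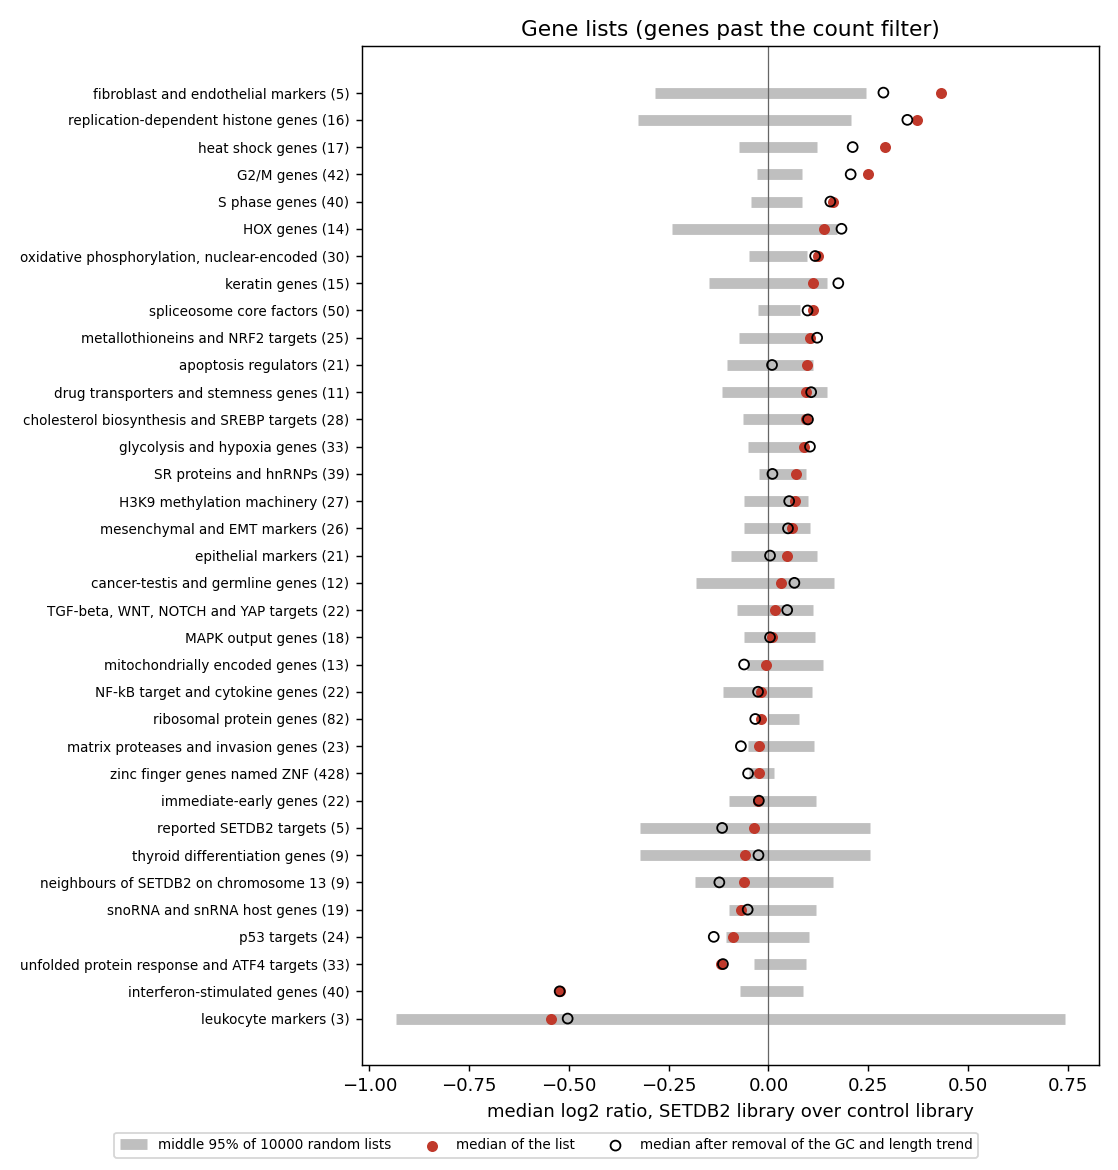
Median log2 ratio of each gene list (red), its median after removal of the GC and length trend (open circles) and the middle 95% of matched random lists before that removal (grey bars); the number of measured genes is in brackets. Interferon-stimulated genes lie below their grey bar and heat shock and cell cycle genes above theirs.

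The log2 ratio followed the GC content of the genes. Across 10234 genes with at least 500 counts, which are not independent replicates, the Spearman correlation of the ratio with GC content was -0.41. The median ratio went from 0.13 in the tenth of genes with the lowest GC content to -0.13 in the tenth with the highest. In 13 of 23 chromosomes the median lay outside the middle 95% of random draws. Chromosome 22 (-0.10) and chromosome 16 (-0.07) were lowest and chromosomes 18 and 4 (both 0.07) highest. With the trend removed, 10 chromosomes lay outside the range, medians ran from -0.04 to 0.03, and chromosome 19 went from -0.04 to 0.02. Before removal 10 of 35 gene lists lay outside the middle 95% of random lists, and all 10 stayed outside afterwards, together with 9 others. With 1 library each, this trend cannot be assigned to the cells or to the preparation of a library. Ratios from the deposited FPKM and from the counts had a Spearman correlation of 0.9989 across genes, high by construction, since each FPKM is a rescaled count. Of these genes 269, none with a ratio above 0.008 in size, differed in direction.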

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

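The alternatives that remove the GC and length trend, keep genes with at least 50% unique pieces, add the counts of U2AF1 and its copy, or leave U2AF1 out of its list's median or mean were chosen after the data were seen, and the others before. Depth limits the low genes most. The 95% counting interval of a gene with 200 counts split evenly reaches 1.33-fold. With 50 counts split evenly it would reach 1.81-fold, but the rule of 1 CPM leaves such a gene out. Under the alternatives chosen before, the SETDB2 ratio ran from 1.40 to 1.44 and the U2AF1 ratio from -1.96 to -1.84. Adding the copy moved the U2AF1 ratio to -1.38 by construction. The median of the spliceosome list stayed above random lists under every alternative except the mean, which was 0.055 inside their range. Without U2AF1 the mean was 0.096, at percentile 99.88, and the median 0.13.

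The numbers of genes higher and lower followed the rule by construction. They were 442 and 735 at 1.5-fold, 9 and 13 at 4-fold, 23 and 43 where the interval had to exclude 2-fold, 866 and 1056 without the count filter, 32 and 47 with a summed count of at least 200, and 93 and 137 for protein-coding genes alone. Ratios from FPKM, with a pseudocount that shrinks low genes, gave 84 and 133. With the trend removed they were 138 and 233, of which 132 and 210 were in the original sets, and with at least 50% unique pieces 141 and 219.

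Of 383 list results under the alternatives chosen before, 374 kept their side of the random range. Scaling by total count, DESeq2 or upper quartile shifts all ratios nearly alike, and FPKM ratios rest on the same counts. Such alternatives could hardly move a list, the spliceosome list included, so 374 overstates how much was put to the test. The fibroblast and endothelial list reversed to percentile 2.33 without the count filter, as members with few counts entered it. Trend removal moved 9 lists outside the range, p53 targets (percentile 0.24), matrix proteases (0.48), ZNF genes (0.98) and mitochondrially encoded genes (1.17) below it and keratin (99.66), glycolysis (99.6), metallothionein (99.52), cholesterol (99.18) and HOX genes (98.44) above it. It also reversed chromosome 19, from -0.041 to 0.022. No named gene with a ratio of at least 2-fold changed direction under the alternatives run on it.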

Other observations

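The gene groups in the first 2 paragraphs and the test that adds the counts of U2AF1 and its copy were chosen after the values were seen; the other tests were written before their results were seen, though after the patterns themselves.

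Of 10 genes of the BMP pathway, which signals through SMAD1, SMAD5 and SMAD9, 2 passed the 2-fold rule as higher in the SETDB2 library. SMAD9 had 128 and 343 counts, a ratio of 1.41 (1.12 to 1.72), and the transcription factor gene ATOH8 142 and 331, a ratio of 1.21 (0.93 to 1.51). The inhibitors of differentiation ID2 and ID3 had 0.65 (0.58 to 0.71) and 0.49 (0.43 to 0.55). BAMBI, a decoy receptor, went the other way at -0.36 (-0.55 to -0.17), and the intervals of SMAD7 (-0.01 to 0.13) and HEY1 (-0.09 to 0.11) held 0. A further group held genes of hemidesmosomes, which anchor epithelial cells to the basement membrane, and 4 keratin genes. Of its 11 measured members ITGB4 and KRT16 passed the 2-fold rule as lower. The basal keratins KRT5 (6 and 1 counts) and KRT14 (5 and 4) did not pass the count filter. ITGB4 had a ratio of -1.18 (-1.32 to -1.05), LAMA3 -0.66 (-0.72 to -0.59) and COL17A1 -0.53 (-0.68 to -0.39), while ITGA6 was at -0.02 (-0.07 to 0.02) and DST at 0.05 (0.02 to 0.08). Keratins did not share a direction. KRT17 was at -0.74 (-0.91 to -0.58) and KRT15 at 0.57 (0.33 to 0.82), and 12 of the 15 keratins in the list fixed beforehand lay above 0.

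Of 14 antigen presentation genes none passed the 2-fold rule and 11 lay below 0, some of them close to it, such as B2M at -0.04 (-0.07 to -0.01). HLA-B was at 217 and 115 counts, a ratio of -0.92 (-1.26 to -0.59), and the immunoproteasome genes PSMB9 and PSMB8 were at -0.61 (-0.79 to -0.43) and -0.53 (-0.67 to -0.40). Of 9 chemokine and complement genes, 6 passed the count filter, all of them below 0 and 5 past the 2-fold rule, with CXCL11 at 139 and 53 counts. Of those the filter left out, CXCL10 had 8 and 12 counts and CFB 26 and 15, and both intervals held equality. CXCL9 had no counts. These groups were assembled from genes seen to differ, so a comparison of them with random lists would carry no weight and is not given. A further group assembled in the same way, the serpin B genes, the family of SERPINB2, went both ways, with 4 above 0 and 5 below.

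U2AF1 was lower in the SETDB2 library, and its near-identical copy was higher. A plain exchange of reads between them is argued against by their sum, whose log2 ratio was -1.38 (-1.52 to -1.25). Uneven handling of shared reads stays open. Of 129 genes with under 20% unique pieces 15.5% passed the 2-fold rule, against 2.33% to 10.08% in matched sets of unique genes. Those 129 include 11 on chromosome 21, U2AF1 among them, of which 6 passed. Outside chromosome 21, 14 of 118 passed, or 11.86%, and no matched range was drawn for them. A lower level of U2AF1 transcripts in cells with SETDB2 could produce the lower sum, but alone not the rise of the copy from 92 to 215 counts. A measurement that does not depend on how shared reads are assigned would be needed to tell.

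Interferon-stimulated genes were lower as a group. GC and length bias is argued against as the whole cause, since the median was -0.52 with that trend removed, against -0.06 to 0.07 in random lists. A stronger interferon response to the vector or to handling in the control culture cannot be told apart from an effect of SETDB2, because the design has 1 culture of each kind. The summed counts of 18 interferon ligand genes, 40 and 44, gave a log2 ratio of 0.13 (-0.52 to 0.79), nearly all from IFNE, too few to decide. A repression of these genes by SETDB2 may be tested in replicate cultures.

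Cell cycle, heat shock and oxidative phosphorylation genes were higher as lists by small amounts, although 2 G2/M, 5 S phase and 3 oxidative phosphorylation genes lay below 0. GC and length bias is argued against as the whole cause, since with the trend removed the medians were 0.21 for G2/M, 0.16 for S phase, 0.21 for heat shock and 0.12 for oxidative phosphorylation genes, each above its random range. With the trend removed 19 of 35 lists lay outside their range, so that position alone sets these lists little apart. A difference in growth state or cell density between the 2 cultures stays open and was not tested, as does an effect of SETDB2. AURKA, at a log2 ratio of 1.23, lay far above the rest of the G2/M genes, whose next member was at a log2 ratio of 0.45. No explanation for AURKA was tested.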
